A study of Mus musculus with 47 samples.

How the data were processed

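Retinas of mice were dissected under dim red light, polyadenylated RNA was selected with poly-T beads, and cDNA libraries were primed with random hexamers, per the labels' protocols. The submitters' processing notes name FastQC 0.23.4, HISAT2 2.2.1 and Subread 2.0.6 and the genome build GRCm39, without the role of each. The annotation release and filters are not given in the sources used here. The authors deposited RPKM values, reads per kilobase of exon per M (mega) reads, with 1 column per library and no pooling. Per the labels, the authors tested differential expression with edgeR and rhythms with MetaCycle and CircaCompare. The RPKM values are not counts, so limma was used here with the same thresholds, and a cosinor took the place of the rhythm packages, which were not used here.

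Values of 47 libraries were used for 57180 genes, and 1 further column that matched no sample was not used. Groups come from age and time in the labels. The labels name 4 mice per group at each time and 1 eye per mouse. Gene symbols were found for 51884 identifiers in GENCODE M21, and 5296 had none. That annotation belongs to an earlier build than GRCm39, so it served for names, biotypes and exon lengths only, and no coordinates are given.

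The low values of a gene are whole multiples of what 1 read is worth, so library totals and reads could be recovered. With exon lengths, and for genes whose length differs between releases the smallest length that made every value whole, reads within 0.01 of a whole number resulted for 37323 of 37323 genes above 0, and they summed to 99.99 to 100.0% of each implied total. Such a length is chosen to give whole reads, so this share is partly built in for those genes. Totals ran from 32.0 to 55.5 M reads, with a median of 37.0 M and a next highest of 46.5 M. Replicates within groups differed by more than sampling noise, with a mean chi-square per gene of 7.02 to 635.64 over 69 pairs, so none was counted as a repeat deposit.

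Genes with at least 0.5 RPKM in at least 12 libraries were tested (15321, of which 457 lack a symbol) on log2(RPKM + 0.5) with limma 3.58.1 in R 4.3.3, eBayes with trend and Benjamini-Hochberg adjustment. Fold changes are on this scale and understate the change of low genes. Age was tested over all libraries with time as a factor and called at an adjusted p under 0.05 and a fold over 1.5. Ages were also contrasted at each time from a fit of 12 group means, with an F test of the interaction. Rhythm was tested in each age by an F test of 24 h cosine and sine terms, and the difference by the age by cosine and sine terms over all libraries. Amplitude and peak time have delta-method errors. Amplitude ratios and peak shifts were taken over genes rhythmic in a fit shared by both ages.

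There were 38 gene lists: core clock, rod, cone, bipolar, amacrine, horizontal and ganglion cells, Müller glia, astrocytes, microglia, T and B cells, endothelium, pericytes, RPE, lens, cornea, skeletal muscle, blood, complement, antigen presentation, interferon response, gliosis, immediate early genes, chaperones, cholesterol synthesis, antioxidants, visual cycle, dopamine and melatonin, ribbon synapse, complex I, mitochondrially encoded, ribosomal, collagens, cell cycle, senescence, insulin and IGF, sex-linked and substrain genes. Some genes stand in more than 1 list. The 35 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 and again with an estimated one, and for rhythmic members with two-sided Fisher's exact tests. List members were named at an adjusted p under 0.05, whatever their fold, up to 4 per list by smallest adjusted p. Tissue levels were compared by two-sided permutation tests with 100000 resamples, 9 in all, with Benjamini-Hochberg adjustment.

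Tests, thresholds, lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took up to 12 rises and 12 falls among genes called for age, with the same sign at all 6 times, at least 2 RPKM in 1 age and a symbol that is no Gm or Rik clone name or pseudogene, which gave 12 rises and 5 falls. It also took all tested clock genes, of which 1 is counted but its values are not reported here, the 10 largest amplitudes among genes rhythmic in both ages, the 12 smallest p-values for a different rhythm, and 3 genes at each time whose count was over 1.5 times from the median, with the same condition on symbols in each case. The permutation tests of tissue levels, the naming of rhythmic list members and the measures screened for single libraries were chosen after seeing the data.

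Alternatives changed the pseudocount, filter, scaling, replicate block, library weights, tissue covariates, variance moderation, fold minimum, times, rhythm test, threshold and gene choice, and left out each library. Chosen after seeing the data were the removal of young ZT10 replicate 4 and aged ZT6 replicate 3 together, limma voom on the recovered reads, a covariate from within-group variation, gene lists with each library left out, and a peak shift without RPE, lens and blood genes. Other splits of the libraries were counted for each fit, with 100 draws where more were possible.

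The steps were tested on simulated data made of the real means of 15321 genes and whole residual columns in random order, with 200 genes changed in each of 5 simulations. For age, 52% of genes changed 1.5-fold and 98.4% of those changed 2-fold were called. A rhythm of log2 amplitude 0.2 was found for 40% of genes in young and 18% in aged, and one of 0.4 for 77.2% and 62%. Residual columns of both ages were drawn together, so this gap does not measure the real spread of either age. A rhythm of 0.4 that was absent in aged was found as a difference for 47.2%, and one of 0.2 for 8%. Only 200 genes were changed, while 3024 in young and 2207 in aged were called rhythmic in the data. The adjustment for rhythm within each age was therefore stricter in the simulations, and the recovery there can be understated.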

Results

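Messenger RNA was measured by sequencing in whole retinas of C57BL/6 mice, a common inbred laboratory strain, that were 6 weeks old (young) or 20 months old (aged). The mice were kept under alternating light and darkness. Retinas were taken every 4 h at 6 zeitgeber times (ZT), which count hours from lights on, so that ZT2, ZT6 and ZT10 fell in the light and ZT14, ZT18 and ZT22 in the dark. Each age and time held 4 libraries, except aged ZT18 with 3, giving 24 young and 23 aged libraries. The totals implied by the values ran from 32.0 to 55.5 M reads per library, with medians of 37.2 M in young and 37.0 M in aged. The comparisons asked which transcripts differed with age, which cycled over the day at each age, and whether the cycles differed between ages.

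Sex-linked and substrain genes served as checks of the animals. The Y-linked gene Ddx3y was at 8.21 ± 1.45 RPKM (SD, n = 24) in young and 7.94 ± 1.42 RPKM (SD, n = 23) in aged, and Xist, transcribed from the inactive X chromosome of females, did not exceed 0.0289 RPKM in any library. None of the 4 tested sex-linked genes passed the test for age, over all genes or adjusted over the list alone. Of the genes used to tell C57BL/6 substrains apart, Nnt, a mitochondrial transhydrogenase, was at 0.0355 ± 0.0193 RPKM (SD, n = 24) in young and 0.0316 ± 0.0224 RPKM (SD, n = 23) in aged, and none of the 3 tested passed. Leaving out young ZT10 replicate 4 and aged ZT6 replicate 3, which stand apart from the other libraries, 1 gene of each list was lower in aged, Uty (-0.10) and Ide (-0.14).

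Aged retinas held more transcript of Csrp3, a muscle LIM protein, and Glb1l3, a beta-galactosidase-like gene. Csrp3 (ENSMUSG00000030470) rose from 0.95 ± 0.42 RPKM (SD, n = 24) to 4.17 ± 1.37 RPKM (SD, n = 23), a log2 difference of 1.67 ± 0.12 (SE) with an adjusted p of 3.61e-14. Glb1l3 (ENSMUSG00000031966) rose from 18 ± 3.51 RPKM to 47.7 ± 9.43 RPKM, a log2 difference of 1.38 ± 0.07 (SE) with an adjusted p of 1.34e-18. The other named rises were Gsc2, a homeobox gene (1.19 ± 0.13), the unnamed locus AC113104.1 (1.17 ± 0.10), Col4a3, a basement membrane collagen chain (1.11 ± 0.06), Tmem116 (1.1 ± 0.06), Prok1, a prokineticin (1.06 ± 0.08), Pifo (1.05 ± 0.11), Hdc, the histamine-forming enzyme histidine decarboxylase (1.01 ± 0.07), Tff2 (0.92 ± 0.13), Clic6 (0.90 ± 0.09) and the lysozyme gene Lyz2 (0.84 ± 0.16), each a log2 difference ± SE, with adjusted p from 9.08e-19 to 0.000224. Transcripts that fell were led by Crygb, Crygc and Crygd, which encode gamma crystallins of the lens, with log2 differences of -2.75 ± 0.60, -2.67 ± 0.57 and -2.59 ± 0.54 (SE). Apobec2 (-0.81 ± 0.09) and Serinc5 (-0.62 ± 0.07) also fell, and over these 5 falls the adjusted p ran from 3.51e-09 to 0.00261.

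**Figure D1:**
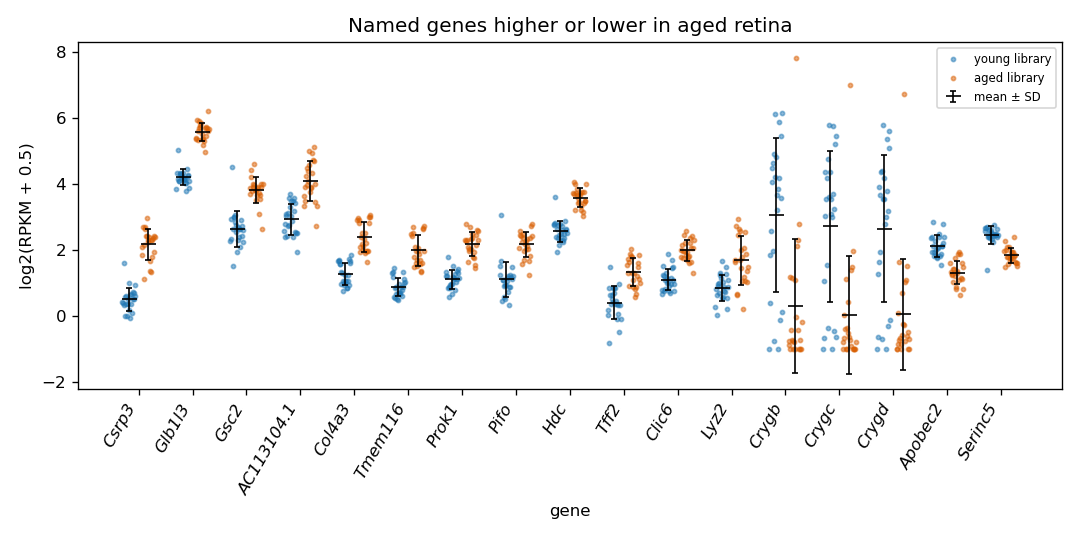
Each point is 1 library at its log2(RPKM + 0.5) on the y axis, for the genes named on the x axis, in young (blue) and aged (orange), and black bars are the mean ± SD over 24 young or 23 aged libraries. Glb1l3 averaged 18 RPKM in young and 47.7 RPKM in aged, while Crygb, Crygc and Crygd spread widely within each age.

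In all, 75 of 15321 tested genes were called for age at an adjusted p under 0.05 and a fold over 1.5, of which 65 were higher and 10 lower in aged. The sign was the same at all 6 times for 70 of the 75. Without the fold minimum 649 genes passed, 369 higher and 280 lower. The share of higher genes among those called was 86.7%, and 88.6% and 88.8% after median-ratio scaling and quantile normalization. The count was 121 with a pseudocount of 0.1, 46 with a pseudocount of 1 and 139 with limma voom on the recovered reads, an analysis chosen after seeing the data. Without young ZT10 replicate 4 and aged ZT6 replicate 3, libraries that stand apart from the others and were chosen after seeing the data, 73 genes were higher and 11 lower. Crygb, Crygc and Crygd are close paralogs, so their separate values are uncertain where the authors' counting could split their reads, and 1 aged library with a high value set the Crygb SD of 46.1 RPKM around an aged mean of 10.6 RPKM.

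Among transcripts of antigen presentation, 5 of 13 tested members rose in aged retinas and 8 did not pass, and 9 rose when adjusted over the list alone. H2-K1, a class I heavy chain, went from 9.46 ± 2.06 RPKM (SD, n = 24) to 15.3 ± 4.46 RPKM (SD, n = 23), a log2 difference of 0.65 ± 0.13 (SE), and Tap2 (0.58 ± 0.10), a peptide transporter, H2-Q4 (0.59 ± 0.12), another class I heavy chain, and Psmb8 (0.32 ± 0.06), an immunoproteasome subunit, also rose. Class I heavy chain genes resemble one another, so reads could be split between them. Of 9 complement genes 3 rose and 6 did not pass, and 5 rose when adjusted over the list alone. They were Cd59a, an inhibitor of the membrane attack complex (0.42 ± 0.05), C1qc (0.47 ± 0.13) and C3 (0.32 ± 0.10). Limma camera with the preset correlation gave adjusted p = 4.02e-11 for antigen presentation and 2.13e-06 for complement. With an estimated correlation both had adjusted p = 0.0988. Leaving out young ZT10 replicate 4 and aged ZT6 replicate 3, 8 antigen presentation and 6 complement genes rose.

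Interferon response, microglial and gliosis lists also held called members. Of 18 interferon response genes 2 rose, Ifi27 (0.58 ± 0.11) and Gbp2 (0.38 ± 0.10), and 5 rose when adjusted over the list alone. Of 9 microglial markers Cd68 alone rose (0.45 ± 0.13), and 3 rose when adjusted over the list alone. Of 17 reactive gliosis genes 4 rose and 1 fell, with the same counts when adjusted over the list alone. Those that rose were Fgf2 (0.28 ± 0.07), Lcn2 (0.34 ± 0.08), Mt2 (0.44 ± 0.12) and A2m (0.49 ± 0.14), and Nes fell (-0.28 ± 0.08). The camera adjusted p was 1.67e-06 for interferon response, 7.36e-05 for microglia and 0.00752 for reactive gliosis, and with an estimated correlation adjusted p = 0.613, 0.59 and 0.83. Without young ZT10 replicate 4 and aged ZT6 replicate 3, 6 interferon response genes and 4 microglial markers rose, and 4 gliosis genes rose and 1 fell, with a camera adjusted p of 0.0827 for gliosis.

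Some markers of tissues next to the retina also differed with age. Of 11 retinal pigment epithelium (RPE) markers Rgr, a retinal G protein-coupled receptor, rose (0.76 ± 0.19), and 5 rose when adjusted over the list alone. Of 5 blood genes Alas2, the erythroid heme synthesis enzyme, rose (0.78 ± 0.22), and all 5 rose when adjusted over the list alone. They moved together, with an estimated correlation of 0.927, so these are not 5 independent rises. The mean log2 level of the blood list in aged and young was 4.68 and 2.85 in the dark, but 2.55 and 2.56 in the light. Hemoglobin genes are close paralogs, so their separate values are uncertain. The hemoglobin transcript Hbb-bs was at 38.5 ± 34.7 RPKM (SD, n = 24) in young and 99.3 ± 109 RPKM (SD, n = 23) in aged and did not pass, with an adjusted p of 0.0857. The camera adjusted p was 0.00153 for RPE and 0.000104 for blood, and with an estimated correlation adjusted p = 0.669 and 0.563. Leaving out young ZT10 replicate 4 and aged ZT6 replicate 3, 4 blood genes rose, Hbb-bs with an adjusted p of 0.0113, as did 4 RPE markers. Of 14 lens genes the 3 gamma crystallins fell and 11 did not pass, over all genes and when adjusted over the list alone, and the lens list had a camera adjusted p of 0.0732 and, with an estimated correlation, adjusted p = 0.974. After median-ratio scaling and quantile normalization the lens list had adjusted p = 0.0379 and 0.0483. The single tested corneal gene, Aldh3a1, differed by 0.81 ± 0.25 with an adjusted p of 0.0533 and did not pass. It passed over its list alone, but with 1 tested member that is no adjustment. Neither of the 2 tested skeletal muscle genes passed.

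With all libraries, markers of retinal neurons and of most metabolic groups did not pass. None of 17 rod, 13 cone, 15 bipolar, 13 amacrine, 7 horizontal or 15 ganglion cell markers changed, over all genes or when adjusted over the list alone. The same held for 6 astrocyte, 7 endothelial and 4 pericyte and smooth muscle markers, 22 heat shock and chaperone, 21 cholesterol synthesis, 20 antioxidant, 19 ribbon synapse, 37 complex I, 13 mitochondrially encoded and 80 ribosomal protein genes. Among 15 Müller glia markers Car2 rose (0.18 ± 0.04), among 17 immediate early genes Atf3 (0.49 ± 0.07) and Fosb (0.18 ± 0.05) rose, and Maob (0.32 ± 0.08) rose among 10 dopamine and melatonin genes. Col4a3 was the 1 called of 12 collagen and matrix genes, Rgr the 1 of 17 visual cycle genes, Gadd45b (0.34 ± 0.09) the 1 of 10 senescence genes and Ighm (0.27 ± 0.07) the 1 of 2 tested T and B cell genes. Igf2bp2 fell (-0.18 ± 0.05) among 13 insulin and IGF genes. Of 10 cell cycle genes Pcna (0.15 ± 0.04) and Tyms (0.13 ± 0.04) rose and Mcm3 fell (-0.21 ± 0.06). Adjusted over the list alone, 2 visual cycle genes rose, 2 cell cycle genes rose and 2 fell, and 1 T and B cell gene rose and 1 fell, with the counts of the other lists in these sentences the same. With the preset correlation the visual cycle and mitochondrially encoded lists also passed camera, with adjusted p = 0.0104 and 0.0473, and with an estimated correlation adjusted p = 0.669 and 0.974. After median-ratio scaling and quantile normalization the mitochondrially encoded list had adjusted p = 0.0842 and 0.524. The 21 lists without a called member held 339 distinct genes, of which 22 had an unadjusted p under 0.05 in limma. Without young ZT10 replicate 4 and aged ZT6 replicate 3, 19 ribosomal protein and 16 complex I genes rose, 7 bipolar cell markers fell and Otx2 rose, and 3 horizontal cell markers fell. Those 4 lists then had camera adjusted p = 2.36e-13, 2.52e-09, 0.00208 and 0.0141, and with an estimated correlation adjusted p = 0.554, 0.554, 0.572 and 0.554. The rod, antioxidant, immediate early and insulin and IGF lists then passed camera too, with adjusted p = 0.0175, 0.00769, 0.0125 and 0.0391, and with an estimated correlation adjusted p = 0.693, 0.554, 0.554 and 0.554. In the same fit 4 visual cycle, 3 immediate early and 2 antioxidant genes and the 1 corneal gene rose, and 5 insulin and IGF genes, 1 cone marker, 1 endothelial marker and 1 cholesterol synthesis gene fell. Rises and falls numbered 1 and 3 for Müller glia, for dopamine and melatonin and for collagens, 1 and 2 for ribbon synapse, 1 and 1 for chaperones, 2 and 1 for senescence and 2 and 2 for cell cycle. The sign of the median log2 difference and the direction of camera's test disagreed for ganglion cells, astrocytes, pericytes, cholesterol synthesis, dopamine and melatonin, collagens, senescence and substrain genes, and the sign of the mean for cell cycle genes, none of which passed camera with all libraries.

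At single times, genes are named in order of adjusted p for ZT2, ZT6 and ZT10, and differences of other genes could be larger, as for Csrp3 at ZT10 (1.50). At ZT6 Tmem116 was higher in aged by 1.38 ± 0.14, Glb1l3 by 1.68 ± 0.17 and Col4a3 by 1.27 ± 0.13 on the log2 scale (SE, n = 4 per age), with adjusted p of 2.51e-08, 4.42e-08 and 4.42e-08. Col4a3 (1.12 ± 0.13), Tmem116 (1.11 ± 0.14) and Zbtb8a (0.92 ± 0.13) had the smallest adjusted p at ZT2, and Col4a3 (1.25 ± 0.13), Tmem116 (1.22 ± 0.14) and Ly75 (1.47 ± 0.19) at ZT10. The counts were 19 at ZT2, 236 at ZT6, 52 at ZT10, 32 at ZT14, 33 at ZT18 and 22 at ZT22. No gene passed the limma test of an age by time interaction. An unadjusted p under 0.05 was found for 735 of 15321 tested genes, no more than chance alone gives at that threshold. Limma voom on the recovered reads also called 0. Array weights called 1597, a count that was not checked against other splits of the libraries.

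The ZT6 excess moved with single libraries. It held 56 genes higher and 180 lower in aged, which became 50 and 35 without young ZT10 replicate 4 and aged ZT6 replicate 3, 76 and 80 after median-ratio scaling and 91 and 91 after quantile normalization. Leaving out aged ZT6 replicate 3 gave 64 genes in all, whereas leaving out aged ZT6 replicate 1, 2 or 4 gave 413, 617 or 710, and leaving out young ZT6 replicate 2, 3 or 4 gave 101, 112 or 147. At ZT2 the count was 8 without aged replicate 1 or 2 or young replicate 3 or 4, and 9 without young replicate 2. At ZT14 it was 52, 16 or 19 without aged replicate 1, 3 or 4, and 20 without young replicate 1. At ZT18 it was 17 without aged replicate 2 and 50 without young ZT10 replicate 4, which shares in the estimate of the spread. At ZT22 it was 8 or 9 without aged replicate 1 or 4, 10, 10 or 12 without young replicate 1, 2 or 3, and 34 without young ZT10 replicate 4.

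Among genes with an established name that were rhythmic in both ages, these 10 had the largest log2 amplitudes summed over both ages. Egr1, a transcription factor induced by neural activity, peaked at ZT 15.98 ± 0.56 h in young and 16.01 ± 0.51 h in aged (SE), with peak-to-trough folds of 13.2 and 9.5. Nr4a1 (6.44-fold and 6.94-fold) and Fos (4.74-fold and 3.75-fold), also immediate early genes, peaked between 16.28 and 17.36 h. Irf7, an interferon regulatory factor, peaked at 19.05 ± 0.24 h and 18.36 ± 0.24 h (SE), with folds of 5.34 and 8.37. Rpe65, the visual cycle isomerase, swung 3.88-fold and 6.91-fold, Ttr, which carries thyroid hormone and retinol-binding protein, 3.71-fold and 6.08-fold, Rgr 3.77-fold and 5.97-fold, Ptgds, a prostaglandin D synthase, 3.24-fold and 6.32-fold, and Serpine3 2.56-fold and 5.69-fold. Rpe65, Ttr and Rgr are members of the RPE marker list, whose mean level was itself higher in the dark at both ages. Rbm3, a cold-inducible RNA-binding protein, peaked in the light at 9.13 ± 0.24 h and 9.58 ± 0.41 h (SE), with folds of 3.45 and 3.39. Over these 10 genes the adjusted p for rhythm ran from 1.5e-09 to 0.0324 in young and from 9.26e-09 to 0.0202 in aged.

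By the 24 h cosinor, 3024 genes were rhythmic in young and 2207 in aged at an adjusted p under 0.05. Both ages shared 1158, where independent lists of those sizes would share 436. Of the shared genes, 96.1% peaked within 3 h of each other in the fits of both ages. Young peaks clustered in the bins centred on ZT6 (1269 genes) and ZT10 (975 genes), with 440 at ZT18, and aged peaks at ZT6 (644), ZT10 (588) and ZT18 (614). The young count was 5207 without young ZT10 replicate 4 and 7069 with array weights, and 1562 with RPE and lens levels as covariates. The aged count was 4188 without aged ZT6 replicate 3, 6023 with array weights and 301 with those covariates, and the shared count was 1972 without aged ZT6 replicate 3, 4229 with array weights and 201 with the covariates.

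Of 21 tested core clock genes, 8 were rhythmic in young, 10 in aged and 6 in both, and 12 in each age without young ZT10 replicate 4 and aged ZT6 replicate 3. The 6 were Rorb, Per1, Per2, Cry1, Bhlhe41 and Nfil3. Rorb, a retinoid-related orphan receptor, had the largest log2 amplitude of them, 0.51 ± 0.04 in young and 0.56 ± 0.09 in aged (SE), with peaks at 18.5 ± 0.31 h and 19.17 ± 0.57 h. Per1, a repressor of the clock, peaked at 15.11 ± 0.79 h and 14.48 ± 0.73 h, Per2 at 14.55 ± 1.01 h and 16.06 ± 0.83 h, Cry1 at 14.5 ± 0.93 h and 14.75 ± 0.93 h, Bhlhe41 at 12.3 ± 0.80 h and 13.65 ± 0.66 h, and Nfil3 at 17.64 ± 0.84 h and 16.94 ± 0.99 h.

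Dbp and Per3 passed in young and not in aged, and Nr1d1, Tef and Ciart in aged and not in young. Their amplitudes in young and aged were 0.26 and 0.34 for Dbp, 0.21 and 0.15 for Per3, 0.15 and 0.31 for Nr1d1, 0.10 and 0.19 for Tef and 0.41 and 0.60 for Ciart. Arntl (0.02 and 0.05), Clock (0.06 and 0.16), Npas2 (0.18 and 0.10), Cry2 (0.06 and 0.09), Nr1d2 (0.06 and 0.15), Rora (0.17 and 0.05), Hlf (0.09 and 0.27), Bhlhe40 (0.12 and 0.36) and Usp2 (0.07 and 0.13) passed at neither age. No clock gene passed the test of a different rhythm between ages or of an age difference in level, over all genes or when adjusted over the list alone. In limma 1 clock gene had an unadjusted p under 0.05 for a different rhythm and 3 for level, and the lowest adjusted p for a different rhythm was 0.606. Leaving out young ZT10 replicate 4 and aged ZT6 replicate 3, Dbp passed for rhythm in aged (adjusted p = 0.000573), Nr1d1, Tef and Ciart in young (adjusted p = 0.00956, 0.000229 and 1.16e-05), Rora in young and Nr1d2 in aged, while Per3 still did not pass in aged (adjusted p = 0.17). In that fit 5 clock genes were lower in aged, Nr1d2, Tef, Dbp, Rora and Per3.

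**Figure D2:**
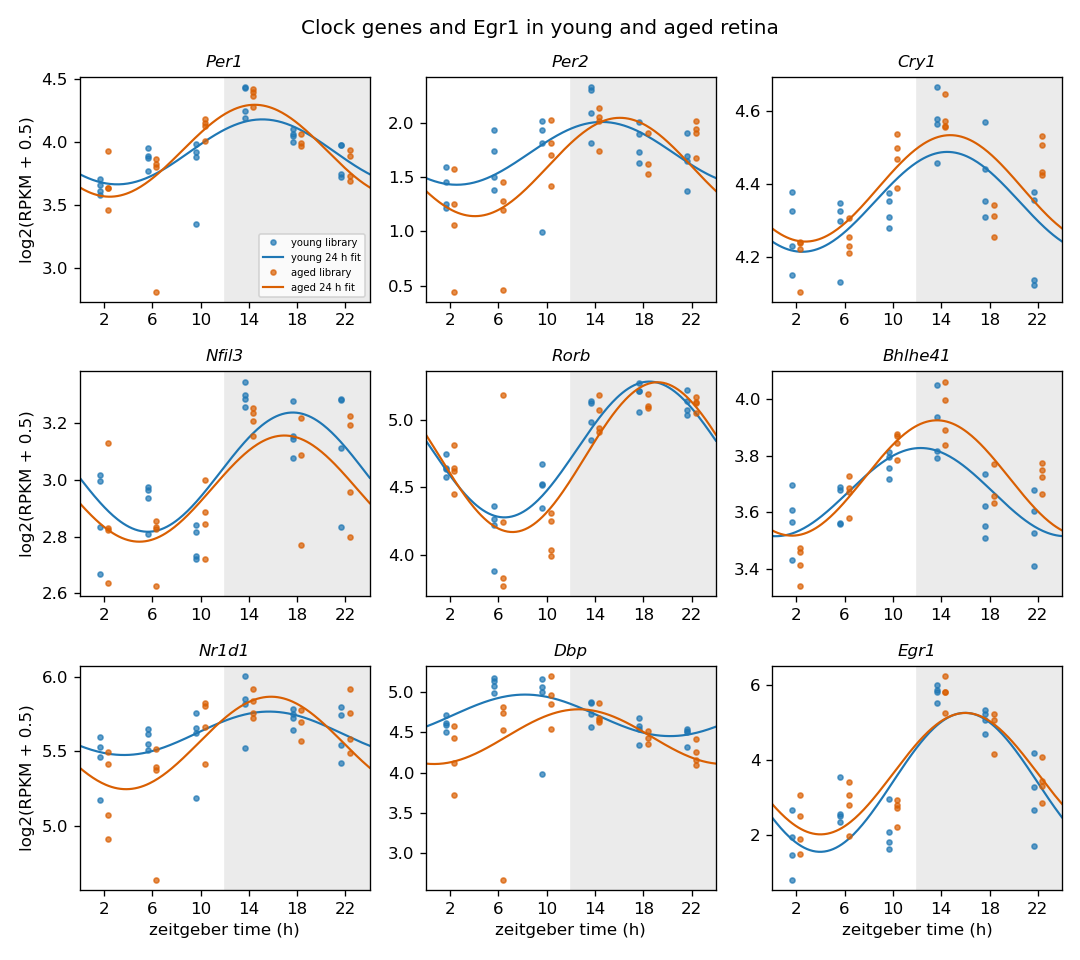
Points are log2(RPKM + 0.5) of single libraries on the y axis against zeitgeber time in h, in young (blue) and aged (orange), lines are the 24 h cosinor fits and grey marks the dark phase. Per1 peaked at 15.11 h in young and 14.48 h in aged, and in the Per1 and Dbp panels 1 aged library at ZT6 and 1 young library at ZT10 lie below the others of their groups.

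Some gene lists were rhythmic more often than other genes. Fisher's exact test counts list members as independent cases, but members can move together, so its p-values here and below can be too small. The estimated correlation was 0.773 for ribosomal proteins, 0.853 for amacrine markers, 0.873 for lens and 0.49 for RPE, but 0.157 for chaperones. Of 22 heat shock and chaperone genes 13 were rhythmic in young and 11 in aged, by Fisher's exact test with adjusted p = 0.00193 and 0.00102. Among them Hspa5, the main chaperone of the endoplasmic reticulum, peaked at 19.68 h and 19.76 h, and Hspa8 at 19.95 h and 19.01 h. Of 17 immediate early genes 9 and 8 were rhythmic, and of 17 visual cycle genes 9 and 8, each list with an exact adjusted p of 0.0272 in young and 0.0077 in aged. Of 11 RPE markers 6 were rhythmic at each age, with an exact adjusted p of 0.0636 in young and 0.0107 in aged. Rpe65, Lrat, Rdh5 and Rgr stand in both the RPE and visual cycle lists, and Per1 in both the core clock and immediate early lists. The core clock list had an exact adjusted p of 0.209 and 0.00254. Of 80 ribosomal protein genes 6 and 1 were rhythmic, fewer than among other genes, with an exact adjusted p of 0.0382 and 0.00102. Of 10 cell cycle genes 6 and 4 were rhythmic, with an exact adjusted p of 0.0415 and 0.118. Leaving out young ZT10 replicate 4 and aged ZT6 replicate 3, the counts were 15 and 17 for chaperones (exact adjusted p = 0.021 and 2.71e-05), 11 and 10 for immediate early genes (0.051 and 0.0464), 10 and 12 for the visual cycle (0.115 and 0.00293) and 7 and 8 for RPE (0.133 and 0.0156). They were 12 and 12 for the core clock (exact adjusted p = 0.115 and 0.0293), 15 and 3 for ribosomal proteins, again fewer than among other genes (0.0332 and 1.74e-06), and 7 and 5 for cell cycle (0.115 and 0.307). In that fit cholesterol synthesis genes, 15 of 21, were rhythmic more often in young (exact adjusted p = 0.021), antigen presentation genes, 8 of 13, in aged (exact adjusted p = 0.0464), and 0 amacrine, lens or mitochondrially encoded genes were rhythmic in young, fewer than among other genes (exact adjusted p = 0.0376, 0.0332 and 0.0376).

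RPE markers were higher in the dark at both ages, and blood transcripts in aged retinas. The mean log2 level of the RPE list was 1.90 ± 0.44 (SD, n = 12) in the dark and 1.17 ± 0.28 (SD, n = 12) in the light in young, by permutation test adjusted p = 3e-04. In aged it was 2.36 ± 0.53 (SD, n = 11) and 1.24 ± 0.33 (SD, n = 12), by permutation test adjusted p = 3e-04. Blood transcripts in aged were at 4.68 ± 1.01 (SD, n = 11) in the dark and 2.55 ± 0.93 (SD, n = 12) in the light, by permutation test adjusted p = 3e-04, and in young at 2.85 ± 0.85 and 2.56 ± 0.99, by permutation test adjusted p = 0.51. All 5 blood genes were rhythmic in aged and 0 in young, by Fisher's exact test with adjusted p = 0.00102 and 0.847. Without young ZT10 replicate 4 and aged ZT6 replicate 3 the exact adjusted p was 0.0133 and 0.358. These genes moved together, with an estimated correlation of 0.927, so they are not 5 independent cases. Alas2 had an adjusted p of 0.606 in the limma test of a different rhythm. Over all times blood was at 3.57 ± 1.44 (SD, n = 23) in aged and 2.70 ± 0.92 (SD, n = 24) in young, by permutation test adjusted p = 0.0383, and the RPE and lens lists had 0.276 and 0.315 between ages. For dark against light the lens list had a permutation test adjusted p of 0.522 in young and 0.27 in aged.

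**Figure D3:**
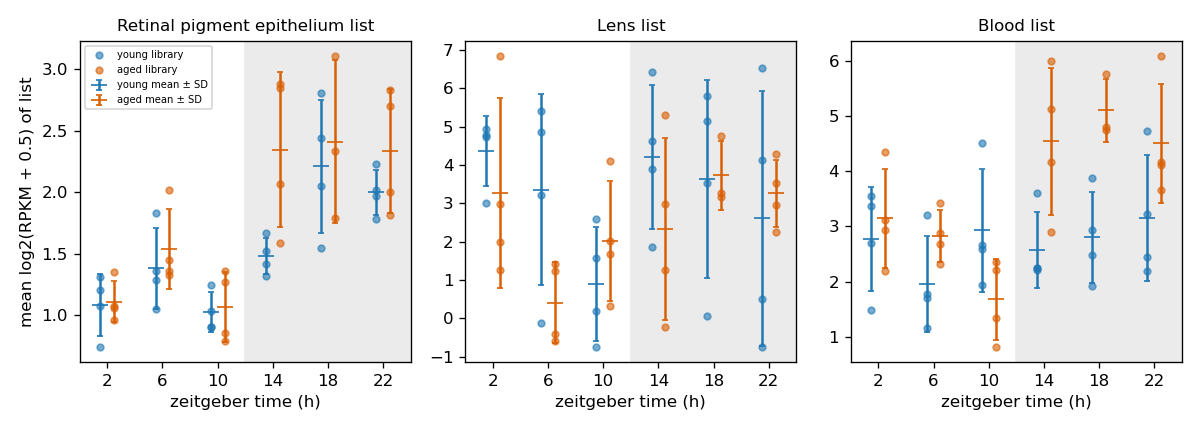
Points are the mean log2(RPKM + 0.5) of a marker list in 1 library on the y axis against zeitgeber time in h, in young (blue) and aged (orange), bars are the mean ± SD of each group and grey marks the dark phase. RPE markers averaged 1.90 in the dark and 1.17 in the light in young, and 2.36 and 1.24 in aged.

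Gas7, a growth arrest-specific gene, was the 1 gene whose rhythm differed between ages. It peaked at 6.79 ± 0.64 h with an amplitude of 0.23 ± 0.04 in young and at 23.47 ± 0.95 h with 0.16 ± 0.04 in aged (SE), with an adjusted p of 0.037 in limma. The next smallest p-values belonged to Armcx6, with an adjusted p of 0.242, and to Gars, Rnf135, Maob, Ttc4, R3hdml, Hadh, Lurap1l, Alas2, Ddx41 and Drg1, each with 0.606. An unadjusted p under 0.05 was found for 1187 of 15321 tested genes, a share that chance alone would put near 0.05. Of 1866 genes called in young alone and 1049 called in aged alone, 0 passed the test of the difference. The Gas7 call was lost in 26 of the 47 fits that left out 1 library. These were aged replicate 2 at ZT2, 1 and 3 at ZT6, 1 to 4 at ZT10, 3 at ZT14, 3 at ZT18, and 1, 2 and 4 at ZT22, and young replicates 2 and 3 at ZT2, 1 to 4 at ZT6, 3 and 4 at ZT10, 4 at ZT14, 2 to 4 at ZT18, and 1 and 4 at ZT22. No gene passed after either scaling, with no filter or with the tissue covariates, and without young ZT10 replicate 4 and aged ZT6 replicate 3 its adjusted p was 0.122.

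Amplitudes and peak times were also compared over rhythmic genes as a set. Over 4633 genes chosen from both ages together, the median log2 ratio of aged to young amplitude was 0.04 with a jackknife SE of 0.18, and the median peak was 0.62 h later in aged with a jackknife SE of 0.39 h. Among the 6 clock genes rhythmic in both ages, 4 peaked later in aged, with shifts from -0.70 to 1.51 h. Over the 1158 genes rhythmic in both ages the median shift was 0.22 h, and with array weights it was 0.16 h.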

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

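The tests of the library that stands apart and of the gamma crystallins were chosen only after those results were seen, as were the test of spread between aged libraries and the classes of markers by the place of their protein. In 11 groups of 4 libraries, 7 measures per library were screened for a library far from the other 3, and 9 of 77 screens found one, where chance finds about 1 in 20.

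Retinal cell markers set young ZT10 replicate 4 apart, as its Müller glia markers averaged 2.02 on the log2 scale, against 4.88 to 4.97 in the other 3 libraries of its group, its RPKM values summed to 324150 against 255447 to 258594, and its mean correlation with all other libraries was 0.8652 against 0.9718 to 0.9745. Relative to those 3 libraries, rod markers for membrane or secreted proteins had a median deviation of -0.22 and those for cytosolic or nuclear proteins 1.14, while inner retinal markers, of Müller glia and inner neurons, were at -3.58 and -2.43. Exon length is argued against as the whole cause, because the gap between rod and inner markers was 3.33 before and 3.55 after a trend on length was subtracted. A loss of transcripts of membrane and secreted proteins is consistent with differences of -1.36 within rod markers and -1.15 within inner markers, but it would not lower inner markers for cytosolic or nuclear proteins, whose median was -2.43. A lower share of inner retina stays open beside it, since the difference of -1.15 neither met nor excluded what it predicts, and no biological explanation was tested.

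Aged ZT6 replicate 3 had 42.44 M reads against 32.54 to 34.18 M in its group and a mean correlation of 0.9021 against 0.9682 to 0.9739. Outside the screen, it had 1919 genes over 2-fold below its group median, and young ZT10 replicate 4 had 3771, against at most 292 in any other library. Genes above 0 numbered 19310 and 19361 in these libraries, at 42.44 and 55.51 M reads, against 22407 to 25267 in the others. The cause was not tested. Aged ZT22 replicate 1 had 46.47 M reads against 36.2 to 37.65 M. Aged ZT14 replicate 3 had an RPKM sum of 278378 against 267514 to 268115. Lens markers averaged 3.00 in young ZT2 replicate 4 against 4.73 to 4.93, and blood markers 3.61 in young ZT14 replicate 1 against 2.21 to 2.25. Gas7 differed in rhythm between ages by the limma interaction test, with an adjusted p of 0.037.

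Gamma crystallin transcripts lay lower in aged retinas than the other lens transcripts did. The mean of Crygb, Crygc and Crygd minus that of 11 other lens markers was -0.49 ± 0.81 (SD, n = 24) in young and -2.98 ± 1.77 (SD, n = 23) in aged, with 22 of 23 aged libraries below the young median. These 3 genes were picked for their fall, so in each resample of the ages the 3 lowest of the 14 lens genes were picked again. Less carried-over lens in aged libraries is argued against as the whole cause, as the real gap of -2.49 lay beyond the lowest resample, -2.15 (permutation p = 1e-05, the smallest possible). An age difference within the lens material present is a candidate explanation, with a gap of -2.17 after the level of the other lens genes was regressed out (permutation p = 1e-05), and which part of the lens was carried over, and reads shared between these paralogs, stay open.

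More genes were called rhythmic in young than in aged, 3024 against 2207, but without aged ZT6 replicate 3 the rhythmic genes in aged numbered 4188, which turns the order, and without both libraries that stand apart the counts were 5207 and 4188. That aged ZT18 had 1 library fewer is argued against as the whole cause, since the lowest young count without 1 of its ZT18 libraries was 2610, or 1.18 times the aged count. Larger spread between aged libraries may contribute, but the median ratio of residual SD, aged over young, decides neither way. It was 1.005 with all libraries and 1.147 without young ZT10 replicate 4 and aged ZT6 replicate 3. The recovery of simulated rhythms does not bear on this, because residual columns of both ages were drawn there in random order. For smaller amplitudes in aged retinas, the prediction written beforehand took a median log2 amplitude ratio that was not negative as evidence against. The ratio of 0.037 met that, but it lay within its SD of 0.063 over other splits, a limit that was not in the prediction. The explanation is therefore left open too. With the spread shared by both ages, the rhythmic genes in young numbered 2779 and the rhythmic genes in aged 2695.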

How the results depend on the processing

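The 17 age differences named first, the only ones followed singly, kept their direction and an adjusted p under 0.05 in all 1020 gene and setting combinations. The fold minimum was not checked there. These genes were picked from the same data as the largest calls, so their steadiness is partly built in. Counts of genes moved under some alternatives. The removal of 2 libraries, voom on the recovered reads, the within-group covariate, gene lists with 1 library left out and the shift without RPE, lens and blood genes were chosen after seeing the data. The cause of the changes below was not tested, except where an alternative's construction gives it. Age calls were 121 (25 lower) with pseudocount 0.1 and 46 (40 higher, 6 lower) with pseudocount 1, since the fold minimum is read on that scale. They were 139 (114 higher, 25 lower) with voom, which also gave 12 at ZT2, 375 at ZT6 and 14 at ZT22. Without a fold minimum, which admits smaller changes, 649 passed (369 higher, 280 lower) and 478 at ZT6. With no filter there were 156 at ZT6, 12 at ZT22 and 0 different rhythms. Median-ratio scaling gave 156 at ZT6 and 0 different rhythms, and quantile normalization 0 different rhythms. Array weights gave 1070, 157, 110, 87, 434 and 88 from ZT2 to ZT22, an interaction count of 1597, rhythmic counts of 7069 in young, 6023 in aged and 4229 in both, 7 different rhythms and a shift of 0.16 h. No other splits of the libraries were run with array weights, so how many of these calls chance would give is not known. RPE and lens covariates gave 86 at ZT6, 12 at ZT14, 12 at ZT22, rhythmic counts of 1562, 301 and 201, and 0 different rhythms. RPE markers themselves cycle, so these covariates can remove rhythm along with carried-over tissue.

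Without young ZT10 replicate 4 and aged ZT6 replicate 3 there were 37, 85, 64, 68 and 41 age calls at ZT2, ZT6, ZT14, ZT18 and ZT22, rhythmic counts of 5207, 4188 and 2969, 0 different rhythms and 16 gene lists, and of the 3024, 2207 and 1158 rhythmic genes, 2992, 2188 and 1154 were called again. The first principal component of variation within groups was also tried as a covariate. It is orthogonal to the group means by construction, so it shrinks the spread without correcting those means and yields too many calls. Its counts were 64, 456, 916, 66, 54 and 102 from ZT2 to ZT22, 2617 for the interaction, 5803, 5063 and 2404 rhythmic and 1204 different rhythms, and they are no evidence for more differences. An F test of any difference among times gave 1004 rhythmic in aged and 609 in both, and an adjusted p under 0.01 gave 1728, 970 and 543. The median shift over genes rhythmic in both ages was 0.22 h. With an estimated correlation 0 gene lists passed. Over all settings, single-gene rhythms lost the call 40 times and gained it 12 times in aged and 43 and 24 times in young. The test of a different rhythm lost it 31 and gained it 12 times over 12 genes. Single lists lost it 30 and gained it 82 times, and 0 of the lists that passed in the main fit were reversed. Reversals were not counted for amplitudes or their ratios.

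Leaving out 1 library gave 68 to 85 age calls (58 to 72 higher, 8 to 14 lower), 8 to 27 at ZT2, 64 to 710 at ZT6, 35 to 75 at ZT10, 16 to 52 at ZT14, 17 to 50 at ZT18 and 8 to 34 at ZT22. It gave 0 to 0 for the interaction, 2610 to 5207 rhythmic in young, 1732 to 4188 in aged and 1002 to 1972 in both, 0 to 1 different rhythms, amplitude ratios of -0.021 to 0.169, shifts of 0.50 to 0.72 h and 8 to 16 gene lists, the 16 without young ZT10 replicate 4. The libraries were taken to share only a replicate number, since over 23 same-numbered pairs across ages correlations of deviations ran from -0.486 to 0.428 and 10 exceeded 0.1, among them all 4 at ZT22 (0.104 to 0.254), where the replicate block left the 22 calls at 22. Numbers shuffled within groups gave some time with all its pairs over 0.1 in 12.2% of shuffles. As a hint that some libraries share more than a number, 19 of 47 lay nearest a library of their own number, against 11.7 on average over the shuffles (permutation p = 0.0193). With the replicate block there were 79 age calls, 17 genes changed with age at ZT2 and 273 genes changed with age at ZT6, and the rhythmic genes in young numbered 2944 and the rhythmic genes in aged 2386, and no count moved by over 1.5 times. Depth limits low transcripts most, since 1 read weighs more in the library of 32.0 M reads than in that of 55.5 M.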

Other observations

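The genes named here, and the counts of splits for genes rhythmic in both ages, the amplitude ratio, the peak shift and the gene lists, were chosen after the results were seen. Drd4, the dopamine D4 receptor gene, cycled with log2 amplitudes of 0.69 ± 0.06 in young and 0.90 ± 0.08 in aged (SE) and peaks at 18.8 h and 18.67 h, and Drd2 also passed at both ages among the 10 dopamine and melatonin genes, whose remaining members passed at neither. Among 10 cell cycle genes, 6 were rhythmic in young and 4 in aged, by Fisher's exact test with adjusted p = 0.0415 and 0.118. Hmgb2 peaked at 5.56 h and 3.33 h, Mcm3 at 8.49 h and 8.79 h and Mcm5 at 10.07 h and 9.98 h. Jchain, an immunoglobulin joining chain gene, peaked at 9.15 h and 9.08 h.

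Cholesterol synthesis genes passed the rhythm test in 3 of 21 cases in young and 4 in aged, with 1 in both, and in 15 and 9 cases without young ZT10 replicate 4 and aged ZT6 replicate 3. Of 37 complex I genes 7 were rhythmic in young and 1 in aged, and 14 and 5 without those libraries. Of 17 gliosis genes 2 and 6 were rhythmic, by Fisher's exact test with adjusted p = 0.847 and 0.0926, and 4 and 9 without those libraries. Edn2, an endothelin, had an amplitude of 0.92 ± 0.13 in young and 0.57 ± 0.22 in aged (SE), and Gfap one of 0.31 ± 0.16 and 0.43 ± 0.10. These counts per age are not tests of a difference between ages.

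Other splits of the same libraries were used to ask how often chance gives results as large. For age, 2 of 100 splits within times, the real one included, called as many genes as the real 75, and the highest other called 92. The count passed at the 5% level, but 1 other split exceeded it, and 100 draws give that share only roughly. For single times, 1 of 35 splits, the real one, reached the real count, with the highest other at 0 for 19 at ZT2, 1 for 236 at ZT6, 8 for 52 at ZT10, 0 for 32 at ZT14, 3 for 33 at ZT18 and 5 for 22 at ZT22, so chance is excluded at the 5% level at each time. A share of 1 of 35 is the smallest these splits can give. The size of the ZT6 count rests on single libraries, as it was 64 without aged ZT6 replicate 3. For gene lists, 56 of 100 splits gave as many as the real 9 lists with the preset correlation, and the highest other gave 24, so chance is not excluded for the number of lists.

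With shuffled time labels, 1 of 100 orders, the real one, reached 3024 genes in young (highest other 1) and 2207 in aged (highest other 1749), so chance is excluded for each. The 1158 in both (highest other 0) follow from those counts, so the 1 of 100 orders that reached them is no test of the overlap. For the age by time interaction the real count was 0, which 100 of 100 splits reach by definition (highest other 1), so the splits test nothing here. For different rhythms 2 of 100 reached the real 1, and the highest other was also 1. The count alone passed at the 5% level, but 1 other split equalled it. The gene behind it, Gas7, lost its call in 26 of the 47 fits that left out 1 library, so chance is not taken as excluded. The median log2 amplitude ratio of 0.037 was reached in size by 62 of 100 splits, the highest other 0.139, and the peak shift of 0.62 h by 8 of 100, the highest other 0.86 h, so chance is excluded for neither.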
